A study of Mus musculus with 9 samples.

How the data were processed

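RNA was sequenced from whole sciatic dorsal root ganglia, the clusters of sensory neuron cell bodies and glia whose axons run in the sciatic nerve, of C57BL/6 mice. Each of the 9 libraries pooled ganglia of 2 mice, collected 24 h after sham surgery or sciatic nerve injury, per the labels' protocols. Young mice were 8 to 10 weeks old and aged mice 20 to 22 months old. RNA with an integrity number above 7.5 was used, and libraries were made with the Illumina TruSeq mRNA kit and sequenced from both ends on a HiSeq instrument, per the labels' protocols.

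The deposited values are FPKM, fragments per kilobase of gene, scaled to the depth of the library, per the file headers and the values. The submitters' processing notes name TopHat2 2.0.12, Bowtie2 2.2.3, SAMtools 0.1.19, HTSeq 0.6.0, edgeR 3.8.6, limma 3.22.7, R 3.1.1 and FastQC 0.10.1 and the genome build mm10, without saying which step each tool did. The annotation release, the handling of strand and the per-library scaling factors are not given in the sources used here. The table held 45904 identifiers, a mix of Ensembl gene and UCSC transcript identifiers, of which 20628 were at 0 in every library. Where both kinds cover the same locus, or genes have near-identical copies, as many immunoglobulin, major histocompatibility complex and hemoglobin genes do, reads could have been split or dropped, so values of single members of these families are uncertain. Each library column was assigned to its sample by the age, treatment and number in its name, and 0 columns were left out.

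Gene symbols and positions came from GENCODE release M21, which uses the same genome build as the deposited table, and 16841 of the 17601 tested identifiers (95.7%) had a symbol. Older symbols in the gene lists were matched through a table of synonyms. FPKM hold no read counts, but the values of a gene were whole multiples of 1 step per gene and library. In 17453 of the 17601 tested identifiers (99.2%), a multiple of up to 20000 brought all values within 0.001 of a whole read. With each value first moved at random, the same search found 27 of them. Recovered reads are known only up to a common factor per gene, and in 81.6% the step lay within a factor of root 2 of that given by the annotated gene length. The FPKM worth of 1 read, relative to young sham replicate 1, ranged from 0.8162 in aged injury replicate 1 to 1.1819 in aged sham replicate 2, which gives the relative depth of the libraries; absolute totals stay open. The reads served for this and for 1 added alternative.

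Genes with a mean of at least 0.2 FPKM over the 9 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1), with a trend of the variance on the mean level. All 9 libraries entered 1 fit, so that the 3 groups of 3 shared 1 estimate of the spread per gene. Tests were two-sided and moderated, p-values were adjusted by the Benjamini-Hochberg method over the 17601 genes tested, and genes with an adjusted p under 0.05 were called. Log2 changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes. The p-values measure the spread between these pools of mice. The 3 comparisons were aged sham against young sham, aged injury against aged sham, and aged injury against young sham.

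The gene lists, the test settings and the rule for the genes named were fixed before the data were examined. From each of the age and the injury comparison the rule took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 FPKM and no overlap of the groups, leaving out symbols of predicted genes, RIKEN clones, micro and small nucleolar RNAs, symbols starting with n-R, ribosomal protein pseudogenes and clone names. It added up to 4 members of each list with the smallest p, and, in each of the 3 comparisons, Cxcl13, Cd8a, Ltb, H2-K1, C4b, Atf3, Sprr1a, Gap43, Jun, Sox11 and Gal. It gave 140 genes for age and 138 for injury, and the text names a part of them. Lists with at least 5 tested members were tested with camera, which asks whether the members of a list moved against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 27 lists. The sex-linked list served only to check the pools, and the list of oligodendrocyte and central nervous system genes had 2 members above the filter and was not tested. Beside camera, each list was tested with the inter-gene correlation estimated from the data and with fry, a rotation test of the list by itself. Within each list, p-values were also adjusted over the list alone.

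Scripts were tested on simulated data with the real genes, their mean levels and their spread. In each, 200 genes with a mean of at least 1 FPKM were changed, so the recovery of lower genes was not tested. Noise was drawn for each gene by itself, without correlation between genes. In the simulated age comparison over 17601 genes, 90% of 100 genes changed 2-fold and 99% of 100 changed 4-fold were called, with 3.6% false calls. In the simulated injury comparison over 17601 genes the shares were 87% and 100%, with 6.5% false calls. In the simulated comparison of injured aged with young sham ganglia, also over 17601 genes, they were 88% and 97%, with 4.6% false calls. A simulated shift of all tested members of the macrophage list ranked first among the lists in each. Since the simulated genes were independent, this does not show how the list tests behave with correlated members.

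The alternatives were pseudocounts of 1 and 0.01 FPKM, no filter and a filter at 1 FPKM, quantile normalization, equal medians of the libraries, fits of the 2 compared groups alone, array weights, the replicate number as a block, and leaving out each library in turn. A limma voom fit on the recovered reads, the share of Y-linked reads as a covariate, and a fit without genes on chromosomes X and Y were added after the data were seen. No library of injured young mice was analysed here, so whether the response to injury differs with age was not tested. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.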

Results

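Gene expression was measured in whole sciatic dorsal root ganglia of mice in 3 groups of 3 libraries: young sham, aged sham and aged injury. Each library pooled 2 mice and was taken 24 h after surgery. Between 20237 and 21100 identifiers were above 0 per library. Genes at a mean of 0.2 FPKM or more, 17601 in all, were compared. The first 3 principal components held 31.8%, 13.5% and 12% of the variance, and the first ran from the young sham libraries (-46 to -41.9) to aged injury replicate 2 (62.1).

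The groups differed in the sex of the pooled mice as well as in age. Xist, the RNA that silences 1 X chromosome in females, was at 0, 0 and 0.02 FPKM in the young sham libraries and between 9.77 and 13.05 FPKM in the aged libraries except aged sham replicate 1, where it was at 1.75 FPKM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty showed the reverse, with Ddx3y at 13.77 to 15.7 FPKM in young sham, 10.88 FPKM in aged sham replicate 1 and at most 0.01 FPKM in the other aged libraries. Over the Y-linked genes, aged sham replicate 1 reached 67.9% of the young mean. The young pools thus held male RNA, 5 aged pools held female RNA and aged sham replicate 1 held both. Every difference between aged and young ganglia below is also a difference between mostly female and male pools.

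The comparison of aged with young sham ganglia asked what age changes without nerve injury. Some genes of myelin fell, and some genes of antigen presentation, complement, macrophages and antibodies rose, while no list as a whole passed with an estimated correlation (adjusted p = 0.491 at best). Pmp22, which encodes a membrane protein of compact myelin (chromosome 11, 63128982 to 63159547), fell from 936 ± 74.0 to 606 ± 15.9 FPKM (SD, n = 3 each), 1.54-fold (SE 0.074 on the log2 scale, limma adjusted p = 0.00966). H2-D1, a major histocompatibility complex class I chain (chromosome 17, 35262730 to 35267499), rose from 69.8 ± 9.96 to 123 ± 10.8 FPKM (1.76-fold, limma adjusted p = 0.0174). Igkc, the constant region of the antibody kappa light chain, rose from 10.6 ± 1.52 to 300.3 ± 230.0 FPKM (limma adjusted p = 0.0344), with 68.5, 528 and 304 FPKM in the aged sham libraries. Cdkn2a, which encodes cell cycle inhibitors that build up in senescent cells, rose 2.59-fold, from 1.58 ± 0.469 to 4.17 ± 0.592 FPKM (limma adjusted p = 0.0253).

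Genes of the glia changed in both directions. Of 14 genes of myelinating Schwann cells, 4 fell, 0 rose and 10 did not pass the test, with 5 falls adjusted over the list alone. Examples besides Pmp22 were Mal, a proteolipid of myelin, and Fa2h, which makes hydroxylated myelin lipids, which fell by 0.50 and 0.49 on the log2 scale. The list was lower against the other genes (camera adjusted p = 4.55e-05; adjusted p = 0.491 with an estimated correlation). Ugt8a, an enzyme that makes the myelin lipid galactosylceramide, fell 2.25-fold, from 36.6 ± 5.82 to 16.2 ± 2.87 FPKM. Of 12 satellite glia genes, 2 rose, 2 fell and 8 did not pass, the same numbers as adjusted over the list alone. Ednrb, an endothelin receptor, fell from 36.1 ± 5.31 to 18.5 ± 0.937 FPKM and the gap junction gene Gja1 from 13.4 ± 2.41 to 7.52 ± 0.33 FPKM. Entpd2, an ATP-degrading ectoenzyme, rose 1.70-fold and Gfap, the intermediate filament of reactive glia, rose 2.73-fold, though only to 1.36 ± 0.0735 FPKM. The satellite glia list as a whole did not pass (camera adjusted p = 0.206).

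Some class I genes of antigen presentation rose with age. Of 17 genes of class I and antigen processing, 6 rose and 11 did not pass, while 16 rose adjusted over the list alone (camera adjusted p = 4.57e-08; adjusted p = 0.491 with an estimated correlation). Examples besides H2-D1 were H2-Q4, up 2.16-fold, H2-M3, up 1.64-fold, and the peptide-loading gene Tapbp, up 1.32-fold. H2-D1, H2-Q4, H2-M3 and Tapbp kept their calls in 5, 3, 1 and 3 of the 9 fits with 1 library left out. H2-K1 had a log2 change of 0.96 with an adjusted p of 0.0535. None of 10 class II genes was called over all genes by limma, with Cd74 at 39.4 ± 2.45 and 102 ± 41.2 FPKM in young and aged sham (adjusted p = 0.0913), but 6 rose adjusted over the list alone. The class II list was higher (camera adjusted p = 0.00152; adjusted p = 0.491 with an estimated correlation). Its mean log2 level above the young mean was 0.623, 2.016 and 1.194 in the aged sham libraries. The T cell list was also highest in aged sham replicate 2 (3.369), and a link between the lists was not tested. Of 22 interferon response genes, Igtp rose 1.35-fold and 21 did not pass, with 4 rises adjusted over the list alone (camera adjusted p = 0.000599; adjusted p = 0.491 with an estimated correlation).

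Genes of complement, macrophages, neutrophils and chemokines were among those that rose with age. Of 13 complement genes, 4 rose and 9 did not pass, with 11 rises adjusted over the list alone: C4b rose from 4.21 ± 0.116 to 8.24 ± 1.47 FPKM, Cfp 2.31-fold, C1qb 2.16-fold and C1qc 2.44-fold. Of 18 macrophage genes, 6 rose and 12 did not pass, with 12 rises adjusted over the list alone. Examples were Tyrobp and Fcer1g, adaptors of activating receptors, up 1.96-fold and 2.04-fold, and the lysosomal marker Cd68, up 2.30-fold. Of 14 genes of neutrophils and bone marrow, 8 rose and 6 did not pass, with 11 rises adjusted over the list alone. The granule protein genes Camp, Ngp and Ltf rose 2.63-fold, 2.63-fold and 2.24-fold. These 3 lists were higher (camera adjusted p = 3e-06, 5.23e-07 and 5e-07), each with an adjusted p = 0.491 with an estimated correlation. No red blood cell gene was called among 8, 1 rose adjusted over the list alone, and the list was higher (camera adjusted p = 0.0295; adjusted p = 0.491 with an estimated correlation). Of 23 chemokine and chemokine receptor genes, 4 rose, 19 did not pass and 10 rose adjusted over the list alone. Ccl8 rose 4.76-fold to 8.31 ± 1.68 FPKM, Cxcl14 to 2.74 ± 1.52 from 0.451 ± 0.0779 FPKM, Cx3cl1 1.95-fold and Cxcl16 1.72-fold. Of 19 genes of lymphotoxin, TNF and NF-kB signalling, Tnfrsf1b rose 2.16-fold and 18 did not pass, with 5 rises adjusted over the list alone. Both lists were higher (camera adjusted p = 0.000486 and 0.000256), again with an adjusted p = 0.491 with an estimated correlation.

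The mean levels of the T cell list and of the B and plasma cell list were above the young mean in every aged library, by amounts that differed widely. Single members were not: Igha was at 0.676 FPKM in aged sham replicate 1 and at 1.04 FPKM or more in young sham. None of 18 T cell genes was called over all genes by limma, and 2 rose adjusted over the list alone. Trbc1, a constant region of the T cell receptor, was at 0.102 ± 0.0882 FPKM in young and 2.74 ± 2.65 FPKM in aged sham (adjusted p = 0.0551). Of 19 genes of B and plasma cells, Igkc rose and 18 did not pass, with 3 rises adjusted over the list alone. The immunoglobulin joining chain gene Jchain was at 0.531 ± 0.148 and 9.80 ± 8.48 FPKM (adjusted p = 0.0506). Both lists were higher (camera adjusted p = 0.000129 and 2.06e-05), each with an adjusted p = 0.491 with an estimated correlation. The mean log2 level of the T cell list above the young mean was 0.666, 3.369 and 1.646 in the aged sham libraries and 1.182, 3.71 and 2.066 in the aged injury libraries. Aged sham replicate 1, the pool with Y-linked reads, was the lowest of the 6. Cxcl13, a chemokine that attracts B cells, was at 0.265, 11.4 and 3.71 FPKM in aged sham and at 0.129, 0 and 0 FPKM in young sham, with an adjusted p of 0.073. Cd8a and Ltb had log2 changes of 2.19 and 2.22 (adjusted p = 0.194 and 0.162), and none of 7 cytotoxic lymphocyte genes was called (camera adjusted p = 0.108). Of the 10 largest rises, 6 were immunoglobulin variable segments: Igkv1-117, at a mean of 0.1451 FPKM in young sham, and Igkv3-4, Ighv9-3, Ighv1-82, Igkv12-46 and Igkv6-17, listed at 0 there. In aged sham replicate 1, Ighv1-82, Igkv12-46 and Igkv6-17 were only at 0.264, 0.224 and 0.448 FPKM. With 1 library left out, Igkv3-4 kept its call in 7 of 9 fits and Igkv1-117 in 4. Ighv9-3, Ighv1-82 and Igkv12-46 kept theirs in 2 and Igkv6-17 in 1.

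**Figure D1:**
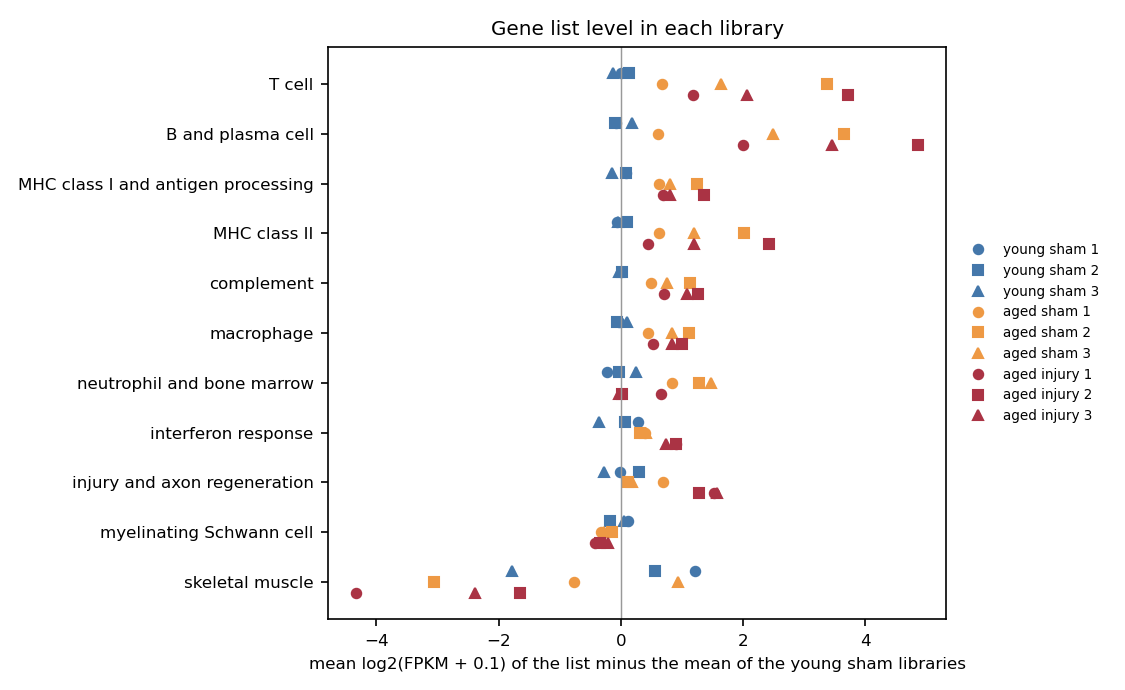
Mean log2(FPKM + 0.1) of the tested members of 11 gene lists in each of the 9 libraries, minus the mean of the 3 young sham libraries (horizontal axis, log2 units); colours mark the group and symbols the replicate number. The T cell list lies between 0.666 and 3.71 in the aged libraries, and the list of injury and axon regeneration genes lies between 1.276 and 1.566 in aged injury against 0.694 at most in aged sham.

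Neuronal genes were among those that changed with age. Of 18 pan-neuronal genes, 2 fell and 16 did not pass, with 4 falls adjusted over the list alone. The sensory neuron transcription factors Pou4f1 and Isl1 fell by 0.39 and 0.33 on the log2 scale, and the list was lower (camera adjusted p = 0.0249; adjusted p = 0.491 with an estimated correlation, and 0.214 after quantile normalization). Of 25 receptors and channels of sensory neuron subtypes, Th rose 1.55-fold and 24 did not pass, with 3 rises adjusted over the list alone (camera adjusted p = 0.141). Among the largest falls were Gabra2, a subunit of the GABA-A receptor (chromosome 5, 70957597 to 71095849), from 32.1 ± 6.95 to 8.50 ± 0.54 FPKM, and the calcium-binding protein gene Calb2, from 13.9 ± 1.39 to 6.72 ± 2.03 FPKM. Tyrp1, an enzyme of melanin synthesis, fell 7.99-fold, from 6.31 ± 1.48 to 0.692 ± 0.102 FPKM (limma adjusted p = 0.000896). Of 29 injury and axon regeneration genes, the neuropeptide gene Npy rose 2.69-fold and 28 did not pass, with 2 rises adjusted over the list alone (camera adjusted p = 0.0523), although the list was called higher after quantile normalization. Of 20 collagen and matrix genes, Lox, which crosslinks collagen, fell 2.92-fold from 7.96 ± 1.33 to 2.68 ± 0.572 FPKM and 19 did not pass, with 5 falls adjusted over the list alone (camera adjusted p = 0.000599; adjusted p = 0.491 with an estimated correlation). Of 9 genes of senescence and its secretory phenotype, Cdkn2a rose and 8 did not pass, with 2 rises adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.491 with an estimated correlation). Of 18 cholesterol synthesis genes, Hmgcs1 and Cyp51 fell by 0.27 and 0.29 on the log2 scale and 16 did not pass, with 2 rises and 5 falls adjusted over the list alone (camera adjusted p = 0.0748). The lists of proliferation, immediate early and heat shock, oxidative phosphorylation, endothelial, adipocyte, skeletal muscle and cartilage and bone genes did not pass (camera adjusted p = 0.0523, 0.108, 0.82, 0.82, 0.82, 0.0852 and 0.82). In these lists Nr4a1, an immediate early gene, rose 1.23-fold and Cldn5, a tight junction gene of endothelial cells, rose 1.30-fold, calls kept in 1 and 0 of the 9 fits with 1 library left out. Among the central nervous system genes, Slc1a2 rose 2.25-fold and Aqp4 did not pass.

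**Figure D2:**
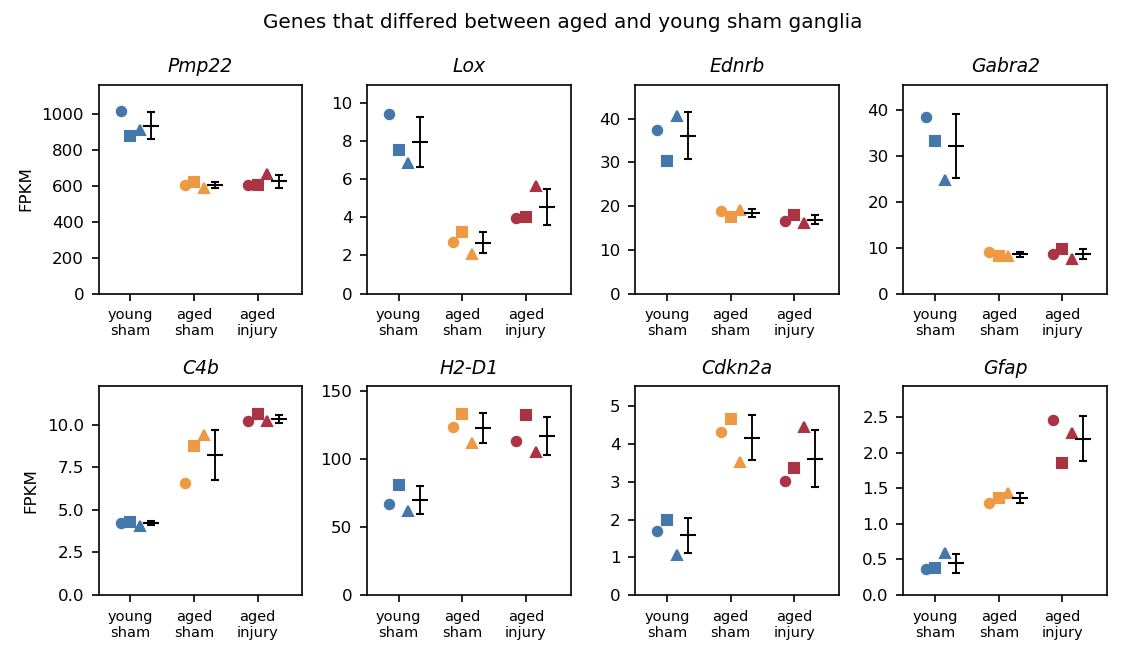
FPKM (vertical axis, from 0) of 8 genes called between aged and young sham ganglia, in young sham, aged sham and aged injury libraries; symbols are the 3 libraries of a group and the black bar is their mean ± SD. Pmp22 falls from 936 to 606 FPKM and Gabra2 from 32.1 to 8.50 FPKM, while C4b rises from 4.21 to 8.24 FPKM.

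In all, 707 of 17601 genes were called between aged and young sham ganglia by limma, 445 higher and 262 lower, of which 111 changed at least 2-fold (90 higher and 21 lower). The balance of directions hung on the scaling: it was 281 higher and 536 lower after the libraries were set to equal medians, 388 and 509 after quantile normalization, and 530 and 535 with limma voom on recovered reads. In 29.2% of the genes the libraries of both groups did not overlap, against 10% by chance. The count was 31 with the 2 groups alone, 101 with the replicate number as a block (80 higher and 21 lower) and 239 with no filter. It was 2020 with array weights, 1065 with voom and 5 with the share of Y-linked reads as a covariate. It fell to 34 without young sham replicate 3, 49 without young sham replicate 1, 39 without aged sham replicate 3 and 50 without aged sham replicate 2. Without aged injury replicates 1, 2 and 3 it was 210, 418 and 229. It rose to 1571 without young sham replicate 2, of which 645 were among the 707 with the same direction. Without aged sham replicate 1, the pool of mixed sex, it was 508, of which 333 were among the 707 with the same direction. Of the 60 called genes chosen by the naming rule, 11 were called with each of the 9 libraries left out in turn, among them Xist, Tyrp1, Gabra2, Lox, Ednrb, Entpd2 and Pmp22. The shifts of 15 lists, 12 up and 3 down, were all lost with an estimated correlation, and regrouping the 6 sham libraries in other ways shifted up to 20 lists. With fry, 4 lists were called, all higher. They were class I and antigen processing (fry adjusted p = 0.0485), and complement, macrophage, and neutrophil and bone marrow (fry adjusted p = 0.0475 each).

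The comparison of aged injury with aged sham ganglia asked how aged ganglia respond 24 h after injury of the sciatic nerve. Sex was not balanced here either. Over the Y-linked genes, aged sham replicate 1 reached 67.9% of the young mean, and each aged injury library 0%. Differences after injury in the full fit are thus also differences between partly male and female pools. Without aged sham replicate 1, the aged libraries compared held no more than traces of Y-linked reads. That fit called 616 genes, against 723 in the full fit, and 482 were shared in the same direction. For these 482 genes the values argue against sex as the sole cause, and for the other calls it stays open. Many genes known to respond in axotomised sensory neurons rose. Atf3, a transcription factor that marks injured neurons (chromosome 1, 191170296 to 191218039), rose from 49.99 ± 39.5 to 247 ± 47.7 FPKM (SD, n = 3 each), a log2 change of 2.55 (SE 0.492, limma adjusted p = 0.0248). Of 29 injury and axon regeneration genes, 23 rose and 6 did not pass, with 24 rises adjusted over the list alone. The transcription factors Jun, Sox11 and Klf6 rose 2.02-fold, 3.14-fold and 1.86-fold, and Flrt3, a membrane protein of axons, rose from 6.75 ± 2.24 to 28.7 ± 3.25 FPKM (limma adjusted p = 0.0043). The list was higher (camera adjusted p = 5.83e-23; adjusted p = 0.448 with an estimated correlation), and it was the single list that fry called (adjusted p = 0.0106).

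Sprr1a, a protein of growing axons, rose from 6.57 ± 1.78 to 20.8 ± 4.07 FPKM, the neuropeptide gene Gal from 33.1 ± 12.7 to 80.1 ± 14.3 FPKM, and Csf1, a growth factor of macrophages and microglia, from 5.56 ± 1.28 to 14.7 ± 1.45 FPKM. Gap43, a growth cone protein, was at 166 ± 11.9 FPKM after sham and 190 ± 18.7 FPKM after injury, with an adjusted p of 0.25. Aged sham replicate 1 stood apart in the list of injury genes: its Atf3 level was 95.6 FPKM against 27.1 and 27.3 FPKM in the other aged sham libraries, and its Gal level 47.6 FPKM against 27.7 and 23.9 FPKM. Among the largest rises outside the list were the growth factor genes Fgf3 and Areg, up by 2.76 and 2.17 on the log2 scale, and the receptor gene Gpr151, up 5.11-fold. Aged sham replicate 1 stood apart in these genes too, with Fgf3 at 1.636 FPKM against 0.231 and 0.267, Areg at 1.555 FPKM against 0.374 and 0.518, and Gpr151 at 7.754 FPKM against 2.36 and 1.76. Without it the log2 changes of Atf3, Fgf3 and Gpr151 were 3.16, 3.535 and 2.98. Igkv17-127, an immunoglobulin variable segment, also rose, from 0.263 FPKM at most in aged sham to 7.08, 28.2 and 1.41 FPKM in the aged injury libraries.

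Some interferon response and cholesterol synthesis genes rose after injury. Of 22 interferon response genes, 4 rose and 18 did not pass, with 10 rises adjusted over the list alone: the antiviral genes Rsad2, Mx2 and Ifit1 rose 2.54-fold, 1.84-fold and 2.33-fold, and Igtp 1.24-fold. Of 18 cholesterol synthesis genes, 4 rose and 14 did not pass, with 10 rises adjusted over the list alone. Sqle, Cyp51, Fdps and Stard4 rose by between 1.20-fold and 1.35-fold. These lists were higher (camera adjusted p = 3.38e-07 and 7.3e-07), each with an adjusted p = 0.448 with an estimated correlation. Of 9 genes of senescence and its secretory phenotype, 3 rose and 6 did not pass, with 4 rises adjusted over the list alone (camera adjusted p = 0.0215; adjusted p = 0.448 with an estimated correlation). Among them were Igfbp3, a binding protein of insulin-like growth factors that rose from 9.22 ± 2.88 to 29.3 ± 5.45 FPKM, and the cell cycle inhibitor Cdkn1a, up 1.61-fold. Bcl3 rose 1.83-fold, alone among 19 genes of lymphotoxin, TNF and NF-kB signalling, with 3 rises adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.727 with an estimated correlation). Mrc1 rose by 0.59 on the log2 scale, alone among 18 macrophage genes (camera adjusted p = 0.744 for the list). Its call was kept in 1 of the 9 fits with 1 library left out. No member of the complement list or of the B and plasma cell list was called by limma, over all genes or adjusted over the list alone. Both lists were nonetheless higher against the other genes (camera adjusted p = 0.0395 and 0.00427), each with an adjusted p = 0.727 with an estimated correlation.

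Neutrophil genes were among those that fell after injury. Of 14 genes of neutrophils and bone marrow, 3 fell and 11 did not pass, with 9 falls adjusted over the list alone. Camp fell from 27.2 ± 7.79 to 12.9 ± 2.95 FPKM, Ngp from 44.9 ± 10.8 to 20.1 ± 6.61 FPKM and Ltf from 12.1 ± 2.6 to 5.37 ± 1.82 FPKM, against 10.1 ± 1.85, 16.9 ± 3.76 and 5.29 ± 0.654 FPKM in young sham. The falls of Camp, Ngp and Ltf kept their calls in 1, 3 and 5 of the 9 fits with 1 library left out. The list was lower (camera adjusted p = 3.38e-07; adjusted p = 0.448 with an estimated correlation). No red blood cell gene was called among 8, 1 fell adjusted over the list alone, and the list was lower (camera adjusted p = 0.00834; adjusted p = 0.479 with an estimated correlation). Of 25 receptors and channels of sensory neuron subtypes, the potassium channel gene Kcns1 fell 1.37-fold and 24 did not pass, with 5 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0341; adjusted p = 0.448 with an estimated correlation, and 0.0957 after quantile normalization). None of 21 oxidative phosphorylation genes was called (camera adjusted p = 0.00427, lower; adjusted p = 0.679 with an estimated correlation). None of 10 skeletal muscle genes was called either (camera adjusted p = 0.017, lower; adjusted p = 0.727 with an estimated correlation), and Acta1, the actin of skeletal muscle, ranged from 1.17 to 107 FPKM over the 9 libraries. The tendon transcription factor Scx fell from 5.58 ± 0.816 to 2.21 ± 0.391 FPKM and the somatostatin receptor gene Sstr1 from 1.70 ± 0.144 to 0.743 ± 0.0772 FPKM. Among pan-neuronal genes Syt4 rose 1.61-fold and Isl1 fell 1.20-fold, among satellite glia genes Glul rose 1.33-fold, among endothelial genes Cldn5 fell 1.46-fold, and among proliferation genes Prc1 rose 1.61-fold (a call kept in 0 of the 9 fits with 1 library left out), with camera adjusted p of 0.487, 0.664, 0.155 and 0.641 for these lists. The lists of T cell, cytotoxic lymphocyte, class I, class II, chemokine, myelinating Schwann cell, collagen, immediate early, adipocyte and cartilage genes did not pass (camera adjusted p from 0.0993 to 0.858), and none of their members was called by limma.

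**Figure D3:**
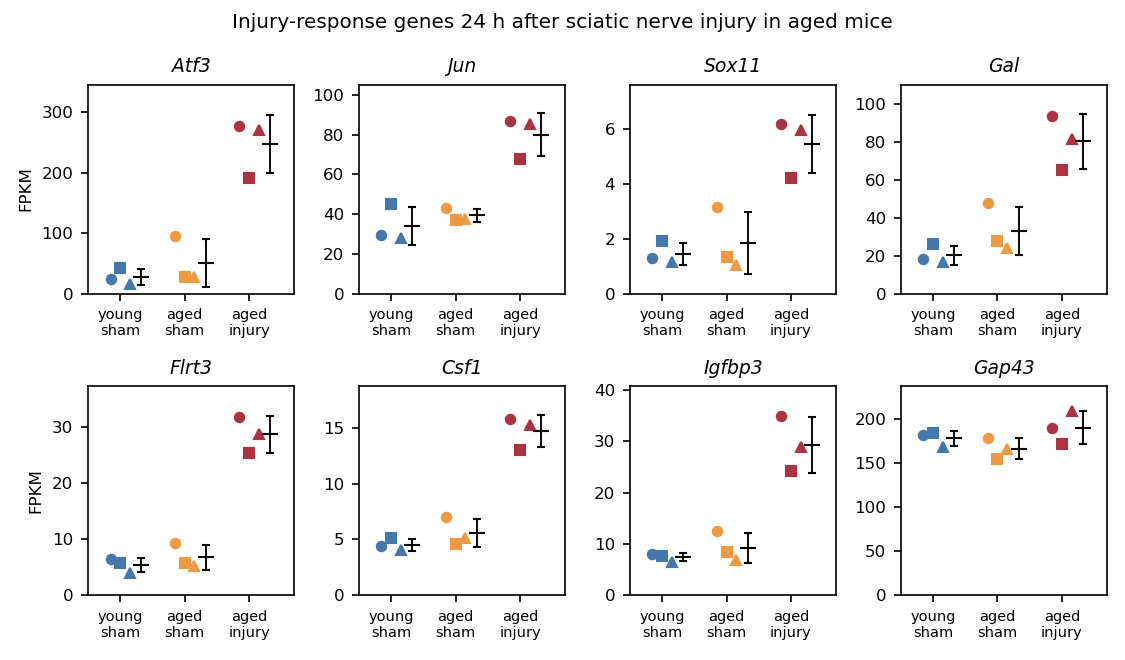
FPKM (vertical axis, from 0) of 8 genes known from nerve injury in young sham, aged sham and aged injury libraries; symbols are the 3 libraries of a group and the black bar is their mean ± SD. Atf3 reaches 247 FPKM after injury against 49.99 FPKM in aged sham, and Gap43 (190 against 166 FPKM) did not pass the test.

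In all, 723 genes were called after injury by limma, 432 higher and 291 lower, of which 93 changed at least 2-fold (81 higher and 12 lower). With the libraries at equal medians the split was 287 higher and 294 lower, and with the 2 groups alone 302 genes were called, 191 higher and 111 lower. With the replicate number as a block, though the numbers are not said to pair the libraries, 273 were called, 197 higher and 76 lower. The libraries of both groups did not overlap in 25.4% of genes, against 10% by chance. The count was 172, 402 and 178 without aged injury replicates 1, 2 and 3, 310 and 210 without aged sham replicates 2 and 3, and 441 without young sham replicate 1; it was 616 without aged sham replicate 1. Of the 45 called genes chosen by the naming rule, 7 were called with each of the 9 libraries left out in turn: Flrt3, Scx, Klf6, Smad1, Csf1, Syt4 and Igfbp3. The shifts of 12 lists, 7 up and 5 down, were all lost with an estimated correlation, regrouping the 6 aged libraries in other ways shifted up to 19 lists, and the count was 6 lists without aged sham replicate 1 and 7 without aged sham replicate 3 or aged injury replicate 2.

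The comparison of injured aged with young sham ganglia holds age, injury and sex together. It called 2304 genes by limma, 1444 higher and 860 lower, of which 412 changed at least 2-fold. The split was 1029 higher and 1670 lower at equal medians and 1168 and 1241 after quantile normalization, and the count was 3755 with array weights and 17 with the share of Y-linked reads as a covariate. Of 29 injury and axon regeneration genes 23 rose, of 22 interferon response genes 16 rose, of 17 class I genes 13 rose, and of 14 myelinating Schwann cell genes 5 fell. Of 14 genes of neutrophils and bone marrow none was called (camera adjusted p = 0.37). Of 27 lists, 20 were shifted with the preset correlation, none with an estimated correlation, and fry called 12. The count of genes was 1032 and 966 without young sham replicates 1 and 3, and 1283 and 957 without aged injury replicates 1 and 3. In 35.4% of genes the libraries of both groups did not overlap, against 10% by chance.

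The age and the injury comparison share the aged sham libraries, which enter them with opposite signs. Over 17601 genes, which are not independent replicates, the log2 changes of both had a correlation of -0.152, against a mean of -0.497 in 100 simulations of unchanged groups. The covariance was -0.0351, against -0.058 simulated. Of the genes called in both comparisons, 79 in number, 47 were higher with age and lower after injury (7.4 for independent lists) and 16 were lower with age and higher after injury (6.4 for independent lists). Another 12 were higher in both (10.9 for independent lists), among them Npy and Igtp, and 4 were lower in both (4.3), among them Isl1. Camp, Ngp and Ltf were among the genes higher with age and lower after injury. The simulations of unchanged groups shared at most 1 called gene over all directions together. Independent lists leave out the shared libraries, which favour opposite directions, and the simulations leave out real effects, so an excess over either is not called a shared effect. The 3 shared libraries are too few to give each comparison its own set, and part of the overlap may come from them.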

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

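Of the 113 called genes taken by the naming rule, 60 for age, 45 for injury and 8 for injured aged against young sham ganglia, 112 kept their call with array weights, 111 with quantile normalization or a pseudocount of 0.01 FPKM, 101 with equal medians or a pseudocount of 1 FPKM, 75 with no filter and 31 with fits of the 2 compared groups alone. With a filter at 1 FPKM, all 110 that were still tested kept it. Of the alternatives added after the data were seen, voom on recovered reads kept 96 of 112, leaving out genes on X and Y kept 110 of 110, and the share of Y-linked reads as a covariate kept 36, with 1 reversed.

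The genes changed with age numbered 707, and 239 with no filter, 31 with the 2 groups alone, 2020 with array weights and 1065 with voom. Those changed after injury numbered 302 with the 2 groups alone, against 723. Those changed between injured aged and young sham ganglia numbered 3755 with array weights, against 2304. Leaving out 1 library gave between 34 (young sham replicate 3) and 1571 (young sham replicate 2) genes for age, 172 (aged injury replicate 1) and 737 (young sham replicate 2) for injury, and 957 (aged injury replicate 3) and 2432 (aged sham replicate 1) for injured aged against young sham. The cause of these moves was not tested.

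The lists shifted with age and after injury, 15 and 12, were 0 and 0 with an estimated correlation and 4 and 1 with fry. With 1 library left out, the lists shifted after injury numbered between 6 (without aged sham replicate 1) and 15 (without aged injury replicate 1).

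The correlation of the age and the injury changes, -0.152, was -0.092 with a pseudocount of 1 FPKM, -0.239 with no filter, 0.018 with a filter at 1 FPKM and -0.045 with voom. It lay between -0.341 (without aged sham replicate 1) and -0.063 (without aged injury replicate 1). The filter at 1 FPKM thus turned its sign. The cause was not tested.

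With the share of Y-linked reads as a covariate, which nearly follows age, 5 genes were called for age, 17 for injured aged against young sham, 9 lists for age and 6 lists after injury. The correlation turned to 0.178. The T cell and the B and plasma cell list turned direction for age (camera adjusted p = 0.773 and 0.374), and the log2 change of Cxcl13 between injured aged and young sham ganglia turned to -0.602. Within the groups only aged sham replicate 1 differed much in this share, so these adjusted values rest nearly on that library. They cannot tell sex from age.

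The replicate numbers are not said to pair the libraries. With the replicate block, 101 genes were called for age (80 higher and 21 lower) and 273 after injury (197 higher and 76 lower), and 62 of the 113 called genes of the naming rule kept their call. As a check, residuals of aged sham and aged injury libraries of the same number had correlations of 0.24, 0.27 and 0.06, and each such library correlated best with its own number in the other group, a hint from the data and not from the design. Between young and aged sham the same numbers had -0.03, -0.07 and -0.05.

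Depth limits what low genes can show: a gene near the filter of 0.2 FPKM rests on few reads.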

Other observations

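Some genes outside the naming rule were chosen after their values were seen. They form no fixed list and were not tested as a group. After injury, the transcription factor genes Scrt1, Isl2 and Pou4f3 fell, Scrt1 from 20.68 to 12.22 FPKM, Isl2 from 77.41 to 50.91 FPKM, and Pou4f3 from 12.95 to 8.276 FPKM (limma adjusted p = 0.00366, 0.0108 and 0.0109). Also lower were Oprl1, the nociceptin receptor, from 7.683 to 4.224 FPKM, Adra2c, an adrenergic receptor, from 5.726 to 3.247 FPKM, and Chrnb3, a nicotinic receptor subunit, from 3.214 to 1.817 FPKM (limma adjusted p = 0.0042, 0.0042 and 0.00802). Bhlhe41, a transcription factor of the circadian clock, rose from 9.166 to 16.17 FPKM. With age, Lgals3, a lectin of activated macrophages, rose from 8.971 to 20.43 FPKM and had the smallest p-value of all genes (limma adjusted p = 0.000501). Tspo, a mitochondrial protein raised in activated macrophages and glia, rose from 11.27 to 21.97 FPKM.

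A few genes, also chosen after their values were seen, were at 0 in all libraries of 1 age. Gm15433, Mirlet7b, Igkv3-4, Ighv9-3 and Igkv6-20 were at 0 in the young libraries and at 0.5 FPKM or more in all 6 aged libraries. Some of these values rest on few reads, so they do not show a gene switched on with age. Mirlet7b is very short (chromosome 15, 85707319 to 85707403) and was at 0.86 FPKM in aged injury replicate 2. Ighv9-3 was at 0.53 FPKM in aged injury replicate 1. The transcript uc029qwo.1 was at 1.38, 1.46 and 1.63 FPKM in the young libraries and at 0 in the aged ones.

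The tests of sex, substrain and lymphoid tissue below were chosen after the results were seen, and the regrouping of libraries was chosen before. For age, 707 genes were called, against 3 at most in the other splits of the 6 sham libraries; for injury 723 against 6; for injured aged against young sham 2304 against 3. The real grouping was in each case the only 1 of 10 with so many calls, and 10 splits are too few for a share under 0.05. Of the 10 splits, 3 shifted at least the 15 lists of the age comparison, the highest other 20, and 5 shifted at least the 12 lists of the injury comparison, the highest other 19. The list counts by themselves therefore do not set the real groupings apart.

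The calls between aged and young sham ganglia could reflect sex as well as age. If sex set them, aged sham replicate 1, with 67.9% of the young Y-linked reads, should lie near the young libraries. Its position from young (0) to the other aged sham libraries (1) was taken over autosomal genes with a mean of at least 1 FPKM called without it. The median over 392 such genes was 0.63 (quartiles 0.40 to 0.87). By the same measure, aged sham replicates 2 and 3 lay at 0.92 and 0.94 over 29 and 16 genes. The genes were chosen anew for each library, so these values are over unlike sets of genes and are not directly comparable. The value for aged sham replicate 1 lies between the predictions and does not decide. No value could have decided, since a decision also required at least 2 aged libraries with Y-linked reads. Only aged sham replicate 1 held more than traces of them, and 1 library can also differ for other reasons. The share of Y-linked reads was also used as a covariate, for 12 genes chosen after their values were seen. The log2 change of Pmp22 went from -0.63 to -0.61, Gabra2 from -1.88 to -1.76 and Cdkn2a from 1.37 to 1.36. C4b went from 0.94 to 0.42 and Igkc from 4.39 to 1.58. None of the 12 kept its call. The SE grew from 0.07 to 0.15 for Pmp22, 0.15 to 0.31 for Gabra2 and 0.22 to 0.47 for Cdkn2a, and stayed at 0.12 for C4b. Within the groups only aged sham replicate 1 differed much in this share, so the adjusted changes rest nearly on that library. The lost calls therefore do not tell sex from age.

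The same measure was taken on the axis from the other aged sham libraries (0) to aged injury (1). It again used autosomal genes with a mean of at least 1 FPKM called without the library in question. Aged sham replicate 1 lay at a median of 0.27 over 556 such genes, against 0.08 and -0.03 for aged sham replicates 2 and 3 over 236 and 186 genes. These values too are over unlike sets of genes and are not directly comparable.

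The spread of the lymphocyte genes between aged libraries might come from sex or from lymphoid tissue taken along in the dissection. Among the 5 aged libraries with no more than traces of Y-linked reads, sham and injured, the T cell list ranged over 2.53 on the log2 scale. This was more than the step of 0.52 from aged sham replicate 1 to the lowest of them. The prediction for sex, that these 5 would be alike, was not met, so sex does not account for the spread among them. Whether the low level of aged sham replicate 1 reflects sex stays open, since it was the only pool with more than traces of Y-linked reads. The T cell list had the same order by replicate number in both aged groups. Its level above the young mean was 0.666, 3.369 and 1.646 in aged sham and 1.182, 3.71 and 2.066 in aged injury. Replicate 1 was thus also the lowest of the aged injury libraries, each with a Y-linked share of 0%. A link of the spread to the replicate number was not tested. Over the 6 aged libraries the markers chosen for lymphoid stroma followed the T cell list with a Pearson r of 0.97 (exact permutation p = 0.0028), and 0.79 without aged injury replicate 2 and aged sham replicate 2, so the prediction for lymphoid tissue as first written, an r of at least 0.8, was met. It does not decide, by a condition added after the result was seen: the stroma chemokines Ccl19 and Ccl21a, whose near-identical copies may lose reads, were at 0 in all libraries but 1 (0.092 FPKM for Ccl19), so the r rests on Cr2 and Fcer2a, which B cells also express. Lymphocytes within the ganglia and attached lymphoid tissue both remain possible.

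The lower Gabra2 in aged ganglia might come from a substrain, since C57BL/6J mice carry a deletion in Gabra2 that lowers its expression, and a deletion in Nnt that C57BL/6N mice lack. Nnt had a log2 change of -0.1 between aged and young sham (95% interval -0.42 to 0.22), which does not match young and aged mice from these different substrains. Other substrain or colony differences stay open, since the Gabra2 deletion is not carried by every C57BL/6J colony. As for sex, aged sham replicate 1 lay at 0.06 of the way from the other aged libraries to the young mean, near the other aged libraries. A condition added after the result was seen, that at least 2 aged libraries hold Y-linked reads, was not met, so sex is not excluded for Gabra2.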
